A study of Rattus norvegicus with 9 samples.

How the data were processed

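RNA was measured by bulk sequencing in primary chondrocytes, the cells of cartilage, from rats of the SD strain. Per the labels' protocols, the cells were routinely grown in DMEM with 10% fetal bovine serum, used at passage 1 or 2, and cultured with rat serum, rat plasma, or rat plasma plus thrombin for 24 hours. Serum is the fluid left after blood has clotted, plasma is the fluid of unclotted blood, and thrombin is the protease that turns fibrinogen into fibrin. Each of the 3 conditions had 3 libraries. RNA was extracted with Trizol and 1 µg of total RNA entered an Illumina library preparation, per the labels. The dose of thrombin, the share of serum or plasma in the medium and the anticoagulant are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

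The authors deposited 1 table with raw counts and FPKM for 18880 Ensembl genes in the 9 libraries. HISAT2, HTSeq 0.11.2 and the rat build Rnor_6.0 are named in the submitters' processing notes, without their roles. The annotation release and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes could not be told apart from their partners. The deposited counts were whole numbers with a different total in each library. The deposited FPKM equalled the count divided by the column total and by 1 whole-number length per gene, for 100% of genes within a relative tolerance of 1e-06. Genes with a count of 0 in all 9 libraries were not in the table. Gene symbols were taken from the table, where 119 gene IDs shared their symbol with another ID. The table gave no gene coordinates, and no genome of that build was used here.

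Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, after TMM scaling and the filterByExpr filter by group with a minimum count of 10, which left 13757 genes. All 9 libraries entered 1 fit with the group as the only term and 6 residual degrees of freedom. The 3 comparisons were plasma against serum, plasma with thrombin against plasma, and plasma with thrombin against serum, each as the former minus the latter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of its F statistic. Levels are CPM, counts scaled to a library of 1e+06 counts, computed from the deposited counts and TMM-scaled library sizes, as mean ± SD over 3 libraries.

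The choices in this and the following sentences were made before the data were examined, except where stated. The text names, for each comparison, the 6 genes with the largest rise and the 6 with the largest fall among called genes with a mean log2 CPM of at least 1, no overlap between the libraries of both groups and a symbol that is not a placeholder. It also names 10 fixed genes whatever their result (Mmp3, Mmp13, Adamts4, Adamts5, Acan, Col2a1, Sox9, Il6, Ptgs2 and F2r) and, for a described list, up to 2 called members in each direction with the largest change. Of the genes this rule names, 1 is not reported here. The 16 pathway lists and 7 lists of markers of other cell types were fixed as well, and 25 of their genes were not in the table. Lists with at least 3 tested members were tested with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 20 lists tested per comparison. Camera compares a list with the other genes. Camera with an estimated correlation and fry, which asks whether the members of a list move one way on balance without comparing them with other genes, were run beside it. The endothelial, platelet and erythroid lists had too few tested members for camera. A further 3 lists (glucocorticoid receptor targets, PPAR and fatty acid oxidation targets, and imprinted genes) were chosen after seeing the data and are used only in the closing section.

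The thrombin difference from plasma was set against the serum difference from plasma across genes by slope, covariance, correlation and overlap of calls. Both differences use the same 3 plasma libraries, so the values were set against 30 simulations with no effect that shared those libraries. How these simulations were read was chosen after the results were seen. Genes are not independent replicates and no p-value was computed for these relations.

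Totals ran from 29924436 to 43962784 counts per library, and the common biological coefficient of variation was 10.3%. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 6.13 to 27.8 between pairs, so no library was counted as a repeat of another. The test was run on simulated counts for the 13757 genes with known changes added. For a 2-fold change, 73.5% of changed genes were recovered for plasma against serum, 71.0% for thrombin against plasma and 74.6% for thrombin against serum. A criterion of 80% recovery of 2-fold changes over all genes, set before the simulation was run, was therefore missed in each comparison. It was replaced, after that result was seen, by the same share among genes with a mean log2 CPM of at least 1, where recovery was 90.7%, 91.1% and 90.7%, together with the absence of calls in the wrong direction, of which there were 0. Over all genes, 1.5-fold changes were recovered in 50.9%, 58.0% and 50.8% and 1.25-fold changes in 19.0%, 18.8% and 13.2% of cases, in the same order. False calls numbered 1, 2 and 5. In these simulations, small changes and changes of genes with few counts were therefore often missed. Far fewer genes were changed there than were called in the data, which makes the adjusted threshold stricter. Recovery in the data may therefore be higher.

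The alternatives were DESeq2 1.42.0 size factors, upper quartile scaling, library size alone, no filter or a stricter filter on low counts, the DESeq2 Wald test, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) from the deposited FPKM, only the 6 libraries compared, the replicate number as a block, each library left out in turn, the 20 most abundant genes left out before scaling, and a minimum 2-fold change. Leaving out the 30 genes whose level rested on 1 library was added after seeing the data. Figures were drawn with matplotlib 3.10.9.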

Results

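Primary rat chondrocytes were cultured for 24 hours with rat serum, rat plasma or rat plasma plus thrombin, with 3 libraries per condition. The title of the series names the role of thrombin in the catabolism of chondrocytes as its subject. Serum libraries held 29924436 to 36900377 counts, plasma libraries 33520890 to 43962784 and plasma plus thrombin libraries 31877264 to 37009972. The 20 most abundant genes took 14.2% ± 0.154 of the counts in serum, 17.4% ± 0.107 in plasma and 16.3% ± 0.186 in plasma plus thrombin (SD, n = 3). On a principal component analysis the first component held 58.4% of the variance and placed serum at -47.1 ± 0.754, plasma plus thrombin at 0.119 ± 0.694 and plasma at 46.9 ± 1.68. The second component, with 11.5%, placed plasma plus thrombin at -24.0 ± 1.24, with serum at 11.9 ± 1.73 and plasma at 12.02 ± 3.58.

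The comparison of plasma with serum asks how the cells differ between both fluids. It cannot separate clotting from the anticoagulant, which is not given, and no culture lacked both fluids. Most listed genes of cartilage matrix were higher in plasma and most of inflammation were lower. Acan (ENSRNOG00000028992), the core protein of the large cartilage proteoglycan, rose 3.45-fold from 2068 ± 70.7 CPM in serum to 7139 ± 490.04 CPM in plasma. Col2a1 (ENSRNOG00000058560), the main collagen of cartilage, rose 3.23-fold, and Sox9, the transcription factor of the chondrocyte lineage, rose 2.81-fold. Mmp3 (ENSRNOG00000032626), a protease that degrades proteoglycans, was 22.9-fold lower, at 9.71 ± 0.87 CPM in plasma against 223 ± 13 CPM in serum. C3 (ENSRNOG00000046834), the central complement component, was 264-fold lower.

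By edgeR's quasi-likelihood test 7383 of 13757 genes differed between plasma and serum, 3733 higher and 3650 lower in plasma. The split turned with the scaling, to 3191 higher and 4467 lower with library size alone and 3089 higher and 4461 lower on log2(FPKM + 1), so the near-even balance rests on the scaling. At least 2-fold changes were seen in 1255 genes higher and 570 lower. Among the 6 largest rises were Fgfr4, a fibroblast growth factor receptor, at 4.93 ± 0.19 on the log2 scale (SE), Slc26a7 at 4.82 ± 0.26, the glutamate receptor subunit Grin3a at 4.82 ± 0.32, the sphingomyelinase Smpd3 at 4.72 ± 0.14 and Olfml2a at 4.40 ± 0.30. Among the 6 largest falls, C3 changed by -8.04 ± 0.15 and the chemokines Cxcl6 and Cxcl3 by -7.47 ± 0.35 and -6.37 ± 0.15. The lipoprotein lipase inhibitor Angptl4 changed by -6.05 ± 0.14 and the siderophore-binding protein Lcn2 by -5.71 ± 0.11. Cxcl6 stood at 0.059 ± 0.055 CPM in plasma, with the lowest library at 0 CPM, so the size of its fall is uncertain. The acute phase protein Orm1 had 1489 counts over the 3 serum libraries and 2 over the 3 plasma libraries, a ratio of 838 with an exact 95% counting interval of 231.5 to 6925, which covers counting error only.

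Of 22 genes of cartilage matrix and chondrocyte identity, 20 were higher and 1 was lower in plasma (camera adjusted p = 2.49e-28). Matn3 rose by 3.12 ± 0.12 and Hapln1, which links aggrecan to hyaluronan, by 2.44 ± 0.10 on the log2 scale. The member that fell was Prg4, the lubricant of the joint surface, at -5.35 ± 0.09. Of 23 inflammatory cytokines and NF-kB targets, 19 were lower and 2 were higher (camera adjusted p = 2.49e-28). Beside C3, the chemokine Ccl20 had 423 counts in serum and 2 in plasma, a ratio of 238 with an exact 95% counting interval of 65.5 to 1972. Il6 was 6.50-fold lower, at 0.127 ± 0.076 CPM against 0.879 ± 0.25 CPM. The 2 members that rose were the adhesion molecules Vcam1, by 2.66 ± 0.32, and Icam1, by 0.24 ± 0.06. Summed markers of leukocytes and macrophages moved with this list, at 49.3 ± 1.80 CPM in serum and 27.9 ± 2.40 CPM in plasma. Their 5 tested members did not pass camera as a list (adjusted p = 0.38), and Cd14 and Cd68 were the 2 called lower. Cd14 made up most of the sum, at a mean of 35.1 CPM over the 9 libraries. Of the other listed markers, Ptprc stood at 0.035 CPM and Adgre1 at 0.031 CPM, so the sum mainly follows Cd14.

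Cholesterol synthesis and uptake was higher in plasma in 19 of 20 genes and lower in 0 (camera adjusted p = 1.37e-17), with Hmgcs1, which makes the precursor of mevalonate, up 4.26-fold and Insig1, a sterol-regulated brake on the pathway, up 3.89-fold. Cell cycle genes were lower in 23 of 26 and higher in 0 (camera adjusted p = 1.54e-08), including the replication helicase subunits Mcm7, by -0.98 ± 0.06, and Mcm3, by -0.88 ± 0.06. Immediate early genes and ERK feedback genes were lower in 15 of 21 and higher in 0 (camera adjusted p = 1.54e-08), led by Fosl1 at -2.54 ± 0.07 and Dusp5 at -1.99 ± 0.14.

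Matrix-degrading proteases were split, with 11 of 21 higher and 9 lower in plasma (camera adjusted p = 0.678). The aggrecanase Adamts4 rose by 2.96 ± 0.22, Adamts9 by 2.50 ± 0.11 and Adamts5, another aggrecanase, by 0.88 ± 0.08, whereas Mmp3 changed by -4.52 ± 0.09, Mmp10 by -4.33 ± 0.17 and the collagenase Mmp13 by -0.56 ± 0.11. Fibroblastic matrix genes were higher in 11 of 17 and lower in 3 (camera adjusted p = 0.00608, and adjusted p = 0.0594 with an estimated correlation), with Col3a1 up 2.43-fold and Dcn at -1.19 ± 0.15. Genes of the unfolded protein and integrated stress response were lower in 8 of 16 and higher in 4 (camera adjusted p = 0.00428, and adjusted p = 0.216 with an estimated correlation). Those that fell most were Trib3, at -1.80 ± 0.08, and Sesn2, at -1.24 ± 0.06, while the transcription factor Xbp1 rose by 0.71 ± 0.07. The prostaglandin synthase Ptgs2 stood at 25.6 ± 2.6 CPM in plasma and 28.4 ± 3.1 CPM in serum (edgeR adjusted p = 0.205). F2r, the main thrombin receptor, rose 1.53-fold in plasma.

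The other lists did not pass camera between plasma and serum. Members higher and lower numbered 10 and 4 of 14 for hypertrophy and mineralization, 7 and 8 of 18 for TGF-beta and SMAD targets, 6 and 9 of 16 for thrombin receptors and coagulation, 7 and 7 of 18 for hypoxia and glycolysis, 6 and 1 of 13 for interferon-stimulated genes, 9 and 7 of 21 for SRF and YAP targets, 5 and 5 of 11 for protease inhibitors and 2 and 3 of 12 for NRF2 and heme response. The thrombin receptor list passed camera when serum replicate 2 was left out (adjusted p = 0.0112). Adjusted over the list alone, the cell cycle list had 24 members lower, the proteases 10 lower, the TGF-beta list 9 lower, the hypoxia list 8 lower, the SRF and YAP list 10 higher and the stress response list 5 higher, and the other pathway counts stayed the same. Median and test differed in sign for the proteases (median 0.37), the protease inhibitors (median -0.18), the hypoxia list (median -0.15) and the NRF2 list (median 0.0058).

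**Figure D1:**
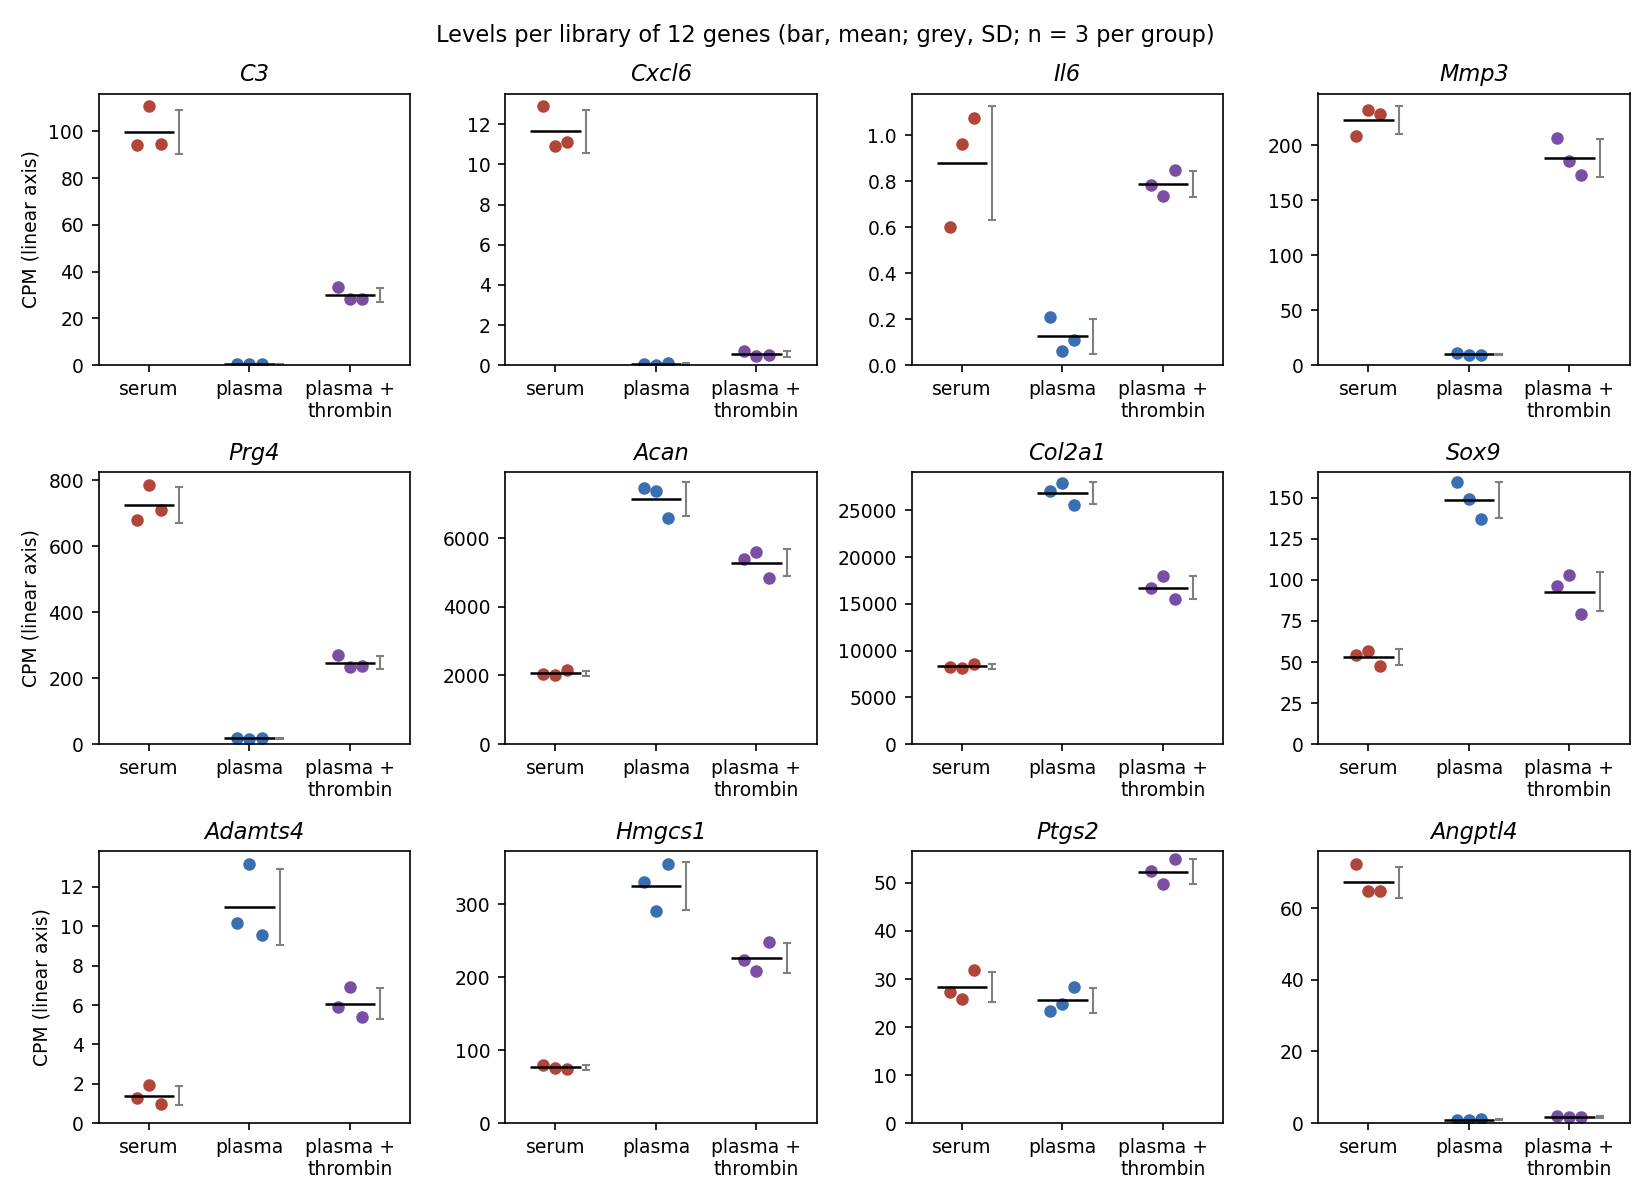
CPM (linear axis) of 12 genes in each of the 9 libraries, with the mean as a black bar and the SD as a grey bar (n = 3 per group). Mmp3 and Il6 lie near their serum level in plasma plus thrombin, Acan, Col2a1 and Sox9 lie between serum and plasma, and Ptgs2 lies above both. Angptl4, at 1.80 ± 0.29 CPM, lies far nearer its plasma level (1.01 ± 0.25) than its serum level (67.2 ± 4.3). Its rise over plasma was still called (edgeR adjusted p = 0.00414).

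Plasma plus thrombin against plasma asks what thrombin adds. Most inflammatory genes, Mmp3 and Mmp10 rose and most cartilage matrix genes fell. Mmp3 rose 19.4-fold, from 9.71 ± 0.87 to 188 ± 17 CPM, and its relative Mmp10 rose 16.2-fold. C3 rose 79.3-fold to 29.96 ± 3.07 CPM. Acan fell by 0.44 ± 0.06 on the log2 scale to 5279 ± 392 CPM, Col2a1 by 0.68 ± 0.05 and Sox9 by 0.68 ± 0.10. The edgeR test called 4018 of 13757 genes, 2005 higher and 2013 lower with thrombin, and at least 2-fold changes were seen in 243 genes higher and 459 lower.

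Among the 6 largest rises, C3 stood at 6.31 ± 0.16, Chi3l1, a secreted glycoprotein of cartilage, at 4.81 ± 0.14, Mmp3 at 4.28 ± 0.09, the secreted phospholipase Pla2g2a at 4.06 ± 0.14 and Mmp10 at 4.02 ± 0.17. Orm1 had 174 counts with thrombin and 2 without, a ratio of 98.6 with an exact 95% counting interval of 26.9 to 820.9. The 6 largest falls were Efemp1, an extracellular matrix protein, at -2.37 ± 0.15, the myosin light chain kinase Mylk at -2.22 ± 0.11, Tril at -2.20 ± 0.21, Cntfr, the receptor of ciliary neurotrophic factor, at -2.14 ± 0.19, the angiotensin receptor Agtr2 at -2.14 ± 0.22 and Rflna at -2.02 ± 0.20.

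Inflammatory cytokines and NF-kB targets rose in 19 of 23 members and fell in 1 (camera adjusted p = 4.48e-42). Ccl20 had 124 counts with thrombin and 2 without, a ratio of 70.3 with an exact 95% counting interval of 19.1 to 586.9. Il6 rose 5.86-fold and Ptgs2 rose 2.05-fold, to 52.4 ± 2.6 CPM, while Vcam1 fell by 1.73 ± 0.30. The summed leukocyte and macrophage markers, mostly Cd14, moved with this list again, to 48.0 ± 0.751 CPM, with Cd14 and Cd68 higher and Csf1r lower (camera adjusted p = 0.279 for the 5 members). The Csf1r call was lost without plasma replicate 1 (edgeR adjusted p = 0.0976), plasma replicate 3 (0.153), or plasma plus thrombin replicates 1 (0.0517), 2 (0.0914) or 3 (0.125), and with the DESeq2 Wald test (0.0833), no filter (0.0566), only the 6 libraries compared (0.0572) and log2(FPKM + 1) (0.067) or log2(FPKM + 0.1) (0.0543). In the cartilage list 20 of 22 members fell and 1 rose (camera adjusted p = 4.73e-20). Cytl1 fell by 1.49 ± 0.11 and Matn3 by 1.41 ± 0.12, and Prg4 was the member that rose, 14.0-fold.

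Immediate early genes and ERK feedback genes rose in 17 of 21 members and fell in 0 (camera adjusted p = 1.87e-19), led by Dusp4 at 1.75 ± 0.14 and Fosl1 at 1.75 ± 0.07. TGF-beta and SMAD targets rose in 11 of 18 and fell in 1 (camera adjusted p = 2.19e-12), with Pmepa1 up 2.58-fold, Ltbp2 up 2.31-fold and the receptor decoy Bambi at -0.71 ± 0.12. Cell cycle genes rose in 18 of 26 and fell in 0 (camera adjusted p = 1.03e-08), with Ccnd1 up 1.55-fold and Birc5 up 1.46-fold. Hypoxia and glycolysis genes rose in 11 of 18 and fell in 2 (camera adjusted p = 1.64e-06), with Egln3 up 3.05-fold, Vegfa up 2.25-fold and Car9 at -0.33 ± 0.07. Cholesterol genes fell in 9 of 20 and rose in 0 (camera adjusted p = 0.000726), with Stard4 at -0.63 ± 0.08 and Hmgcs1 at -0.52 ± 0.08.

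Matrix-degrading proteases rose in 7 of 21 and fell in 7 (camera adjusted p = 0.00446, and adjusted p = 0.0622 with an estimated correlation). Beside Mmp3 and Mmp10, Mmp13 rose 1.41-fold to 90.3 ± 12 CPM. The aggrecanases fell, Adamts4 by 0.85 ± 0.19 and Adamts5 by 0.87 ± 0.08, and so did Adamts9, by 1.62 ± 0.11, and Adamts15, by 1.38 ± 0.13. Thrombin receptors and coagulation genes rose in 8 of 16 and fell in 3 (camera adjusted p = 0.00348, and adjusted p = 0.173 with an estimated correlation), with the inhibitor Tfpi2 up 4.60-fold, the urokinase receptor Plaur up 2.31-fold and Gas6 at -0.95 ± 0.07. F2r stood 0.25 ± 0.08 lower on the log2 scale, at 48.0 ± 3.2 CPM against 57.3 ± 2.6 CPM (edgeR adjusted p = 0.0338). That call was lost without plasma replicate 1 (adjusted p = 0.125), plasma replicate 2 (0.069), or plasma plus thrombin replicate 1 (0.0725) or 2 (0.104), and on log2(FPKM + 1) (0.0524) and log2(FPKM + 0.1) (0.0518).

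Genes of the unfolded protein and integrated stress response rose in 7 of 16 and fell in 3 (camera adjusted p = 0.0234, adjusted p = 0.264 with an estimated correlation and 0.0674 without plasma replicate 3). Trib3 rose 1.97-fold and Sesn2 rose 1.53-fold. Interferon-stimulated genes fell in 4 of 13 and rose in 0 (camera adjusted p = 0.0407, adjusted p = 0.116 with an estimated correlation, 0.0767 with the DESeq2 Wald test and 0.0674 without plasma replicate 3), with Irf9 at -0.47 ± 0.09. The remaining pathway lists did not pass camera. Members higher and lower numbered 4 and 6 of 14 for hypertrophy and mineralization, 6 and 5 of 17 for fibroblastic matrix, 2 and 7 of 21 for SRF and YAP targets, 4 and 5 of 11 for protease inhibitors and 4 and 1 of 12 for NRF2 and heme response. Adjusted over the list alone, 20 inflammatory, 18 immediate early and 19 cell cycle genes were higher, 13 cholesterol, 5 interferon, 4 stress response, 3 hypoxia and 2 TGF-beta genes were lower, the SRF and YAP list had 5 higher and 8 lower, and the other pathway counts stayed the same. Median and test differed in sign for the stress response list (median -0.035), hypertrophy (median -0.40), fibroblastic matrix (median 0.031) and protease inhibitors (median 0.028).

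**Figure D2:**
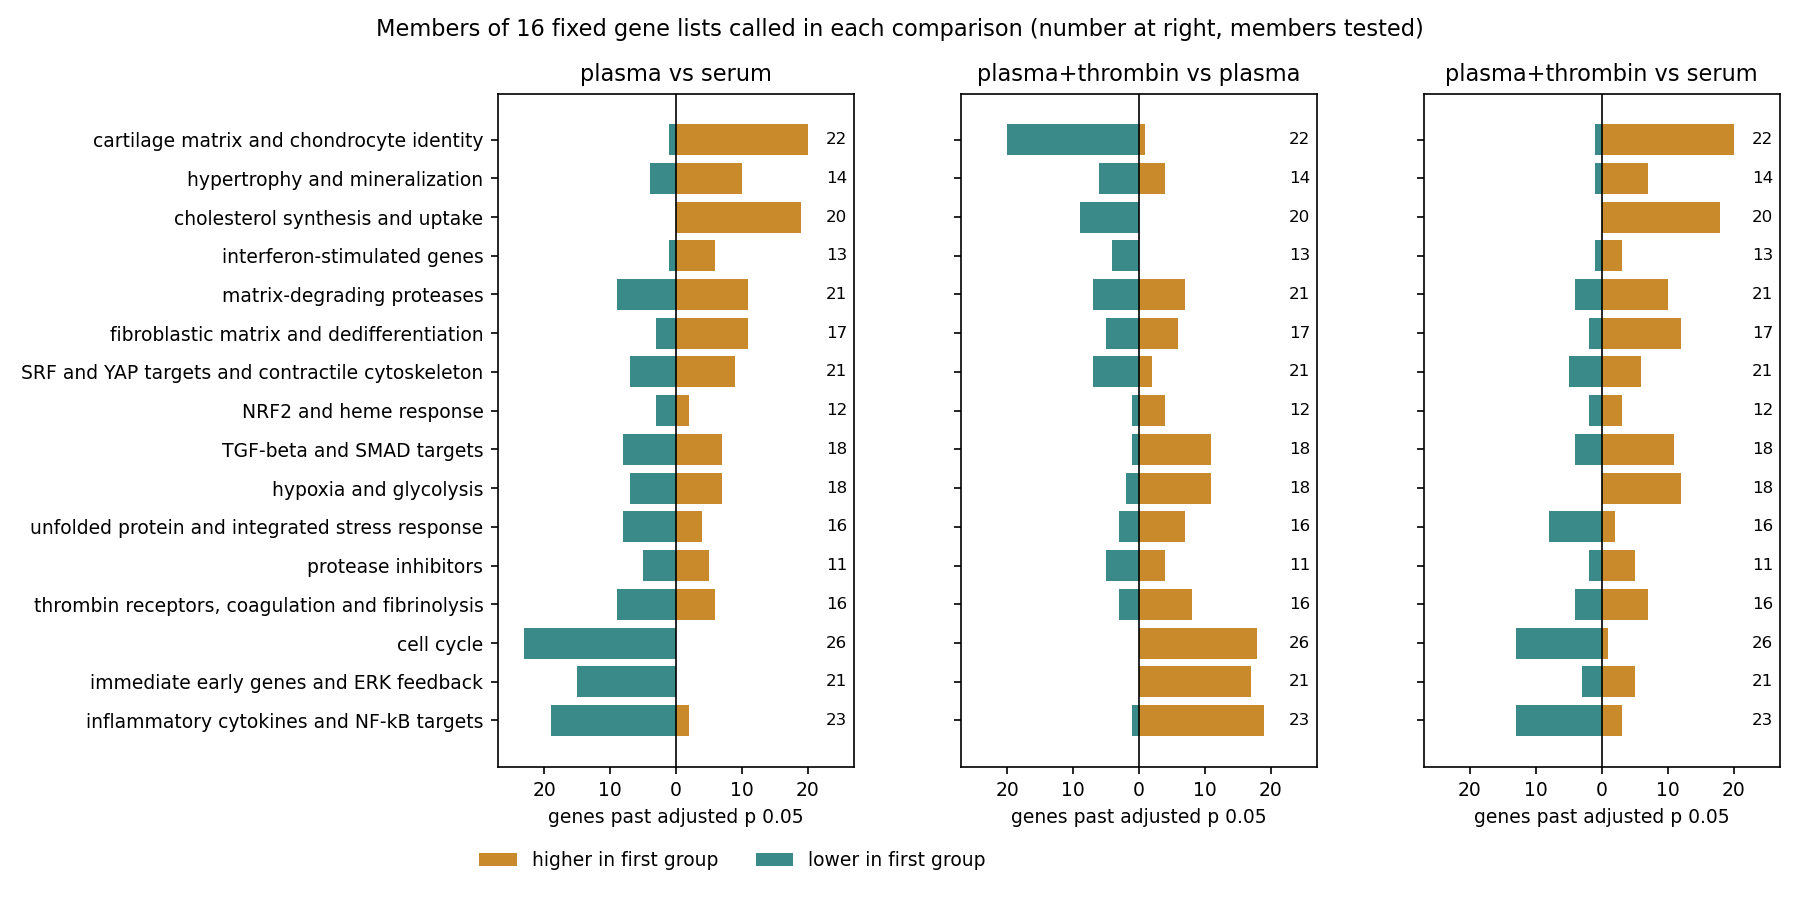
Number of members of each of the 16 fixed pathway lists called higher (right, in the first group named) or lower (left) at an adjusted p under 0.05, with the number tested at the right edge of each panel. Cartilage genes were higher in 20 of 22 in plasma against serum and lower in 20 of 22 in plasma plus thrombin against plasma, and most inflammatory genes moved the opposite way in both.

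Plasma plus thrombin against serum shows how far the plasma cultures with thrombin differed from cultures in serum. Most cartilage and cholesterol genes were higher and 13 of 23 inflammatory genes were lower with plasma plus thrombin. Acan was 2.55-fold, Col2a1 2.01-fold and Sox9 1.76-fold higher than in serum. Mmp3 differed by -0.24 ± 0.08 on the log2 scale (edgeR adjusted p = 0.0349), a call that was lost without serum replicate 2 (0.111) or 3 (0.0982) or plasma plus thrombin replicate 2 (0.0736) or 3 (0.0914). Mmp13 differed by -0.06 ± 0.11, Adamts5 by 0.01 ± 0.08 and Il6 by -0.15 ± 0.35, none of which passed the test. Adamts4 was 4.32-fold, Ptgs2 1.85-fold and F2r 1.28-fold higher with plasma plus thrombin.

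The edgeR test called 3979 of 13757 genes, 2192 higher and 1787 lower than in serum, with at least 2-fold changes in 494 genes higher and 229 lower. The split turned with the scaling, to 1791 higher and 2607 lower with library size alone and 1661 higher and 2576 lower on log2(FPKM + 1), whereas the median of all genes moved by less than 0.1. The 6 largest rises were Grin3a at 4.83 ± 0.32, Fgfr4 at 3.57 ± 0.20, the carbonic anhydrase Car3 at 3.19 ± 0.12, Sh3rf2 at 3.07 ± 0.22, Phyhipl at 3.01 ± 0.21 and Smpd3 at 2.99 ± 0.14. The 6 largest falls were Angptl4 at -5.21 ± 0.13, Cxcl6 at -4.38 ± 0.26, the transcription factor Zbtb16 at -3.62 ± 0.28, Orm1 at -3.04 ± 0.29, Doc2a at -2.99 ± 0.19 and Cttn at -2.96 ± 0.66. Cttn carries 2 gene IDs in the table and ranged from 26.14 to 82.76 CPM between serum libraries, so its value is uncertain.

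Cartilage genes were higher than in serum in 20 of 22 and lower in 1 (camera adjusted p = 2.68e-20), with Matn3 up 3.26-fold, Hapln1 up 2.63-fold and Prg4 at -1.55 ± 0.08. Cholesterol genes were higher in 18 of 20 and lower in 0 (camera adjusted p = 1.28e-26), with Hmgcs1 up 2.96-fold and Insig1 up 2.89-fold. Inflammatory genes were lower in 13 of 23 and higher in 3 (camera adjusted p = 4.28e-11), with the chemokines Cxcl3 at -2.52 ± 0.11 and Cxcl1 at -2.31 ± 0.14. Hypoxia and glycolysis genes were higher in 12 of 18 and lower in 0 (camera adjusted p = 2.37e-09), with Car9 up 3.58-fold and Ankrd37 up 2.85-fold. TGF-beta and SMAD targets were higher in 11 of 18 and lower in 4 (camera adjusted p = 1.76e-06), with Id2 up 3.05-fold, Id3 up 2.30-fold and Serpine1 at -0.79 ± 0.07. Fibroblastic matrix genes were higher in 12 of 17 and lower in 2 (camera adjusted p = 5.52e-05), with Thy1 up 2.15-fold and Lox at -0.66 ± 0.08. Hypertrophy and mineralization genes were higher in 7 of 14 and lower in 1 (camera adjusted p = 0.00076), with the osteoblast factor Sp7 up 4.68-fold and Phospho1 at -0.71 ± 0.11. Sp7 was low, at a mean of 1.11 CPM over the 9 libraries, and is also in the osteoblast marker list. That list had 2 of 4 tested members higher and 0 lower, and did not pass camera (adjusted p = 0.216). Cell cycle genes were lower in 13 of 26 and higher in 1 (camera adjusted p = 0.000254), with Aurkb at -0.46 ± 0.06 and Mcm7 at -0.44 ± 0.06.

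Stress response genes were lower than in serum in 8 of 16 and higher in 2 (camera adjusted p = 0.00731, and adjusted p = 0.186 with an estimated correlation), with Trib3 at -0.83 ± 0.08. Proteases were higher in 10 of 21 and lower in 4 (camera adjusted p = 0.0496, and adjusted p = 0.146 with an estimated correlation), a call also lost without serum replicate 1 (0.0807), serum replicate 3 (0.113) or plasma plus thrombin replicate 1 (0.0532), with upper quartile scaling (0.0504), with library size alone (0.0792) and with only the 6 libraries compared (0.0553). Plat rose 1.98-fold and Plau stood at -0.81 ± 0.10. In all 3 comparisons, the camera calls given without a p for an estimated correlation also held with it, but at much weaker values. For plasma against serum that camera adjusted p was 0.000351 for cartilage and 0.0483 for immediate early genes. For plasma plus thrombin against serum it was 0.0486 for hypertrophy and 0.0412 for cell cycle genes. The remaining pathway lists did not pass camera, with members higher and lower numbering 5 and 3 of 21 for immediate early genes, 7 and 4 of 16 for thrombin receptors and coagulation, 3 and 1 of 13 for interferon-stimulated genes, 6 and 5 of 21 for SRF and YAP targets, 5 and 2 of 11 for protease inhibitors and 3 and 2 of 12 for NRF2 and heme response. The protease inhibitors passed camera without plasma plus thrombin replicate 3 (adjusted p = 0.0463). Adjusted over the list alone, 14 inflammatory, 14 cell cycle, 5 protease, 4 immediate early and 3 NRF2 genes were lower, 13 hypoxia, 12 TGF-beta, 7 SRF and YAP, 6 protease inhibitor and 4 inflammatory genes were higher, and the other pathway counts stayed the same. Median and test differed in sign for the immediate early list (median 0.034), the thrombin receptor list (median 0.25) and the NRF2 list (median -0.024).

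Markers of other cell types were low, and the endothelial sum was mostly Egfl7, at a mean of 11.1 CPM over the 9 libraries. The summed CPM in serum, plasma and plasma plus thrombin was 11.56, 11.998 and 11.53 for endothelium, 0.679, 0.912 and 0.639 for platelets, 0.594, 1.29 and 0.643 for erythroid cells, 1.95, 5.16 and 3.45 for skeletal muscle, 2.17, 4.54 and 3.92 for osteoblasts and 13.3, 8.16 and 7.18 for adipocytes. None of the 4 such lists with enough tested members passed camera in any of the 3 comparisons. For plasma against serum the adjusted p was 0.428 for skeletal muscle, 0.38 for osteoblasts and 0.872 for adipocytes. It was 0.648, 0.739 and 0.471 for plasma plus thrombin against plasma and 0.398, 0.216 and 0.664 against serum, with 0.673 for leukocytes.

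Across the 13757 genes, the thrombin difference from plasma followed the serum difference from plasma with a slope of 0.501, a Pearson correlation of 0.778 and a Spearman correlation of 0.776. Of 3617 genes called in both, 3537 moved the same way, 1712 of them higher and 1825 lower than in plasma. Simulated groups with no effect that shared the plasma libraries had at most 1 such gene in each direction. With no effect almost no gene passes the threshold, so this count cannot show how much of the overlap comes from sharing. Independent lists of the observed sizes would share 532 and 546. The simulated Pearson correlation averaged 0.491, so the correlation alone overstates the relation. The covariance was 0.389, against 0.0273 on average and 0.0309 at most in 30 simulations, which leaves 0.362 and a slope of 0.502 once the simulated parts are taken off. The 3 plasma libraries were not divided between both differences, so part of the excess overlap may come from the shared libraries. Of the 7383 genes that differed between plasma and serum, 1742 differed from both in plasma plus thrombin and lay between them, 1737 differed only from plasma, 1679 differed only from serum, 2087 differed from neither and 138 lay beyond both.

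**Figure D3:**
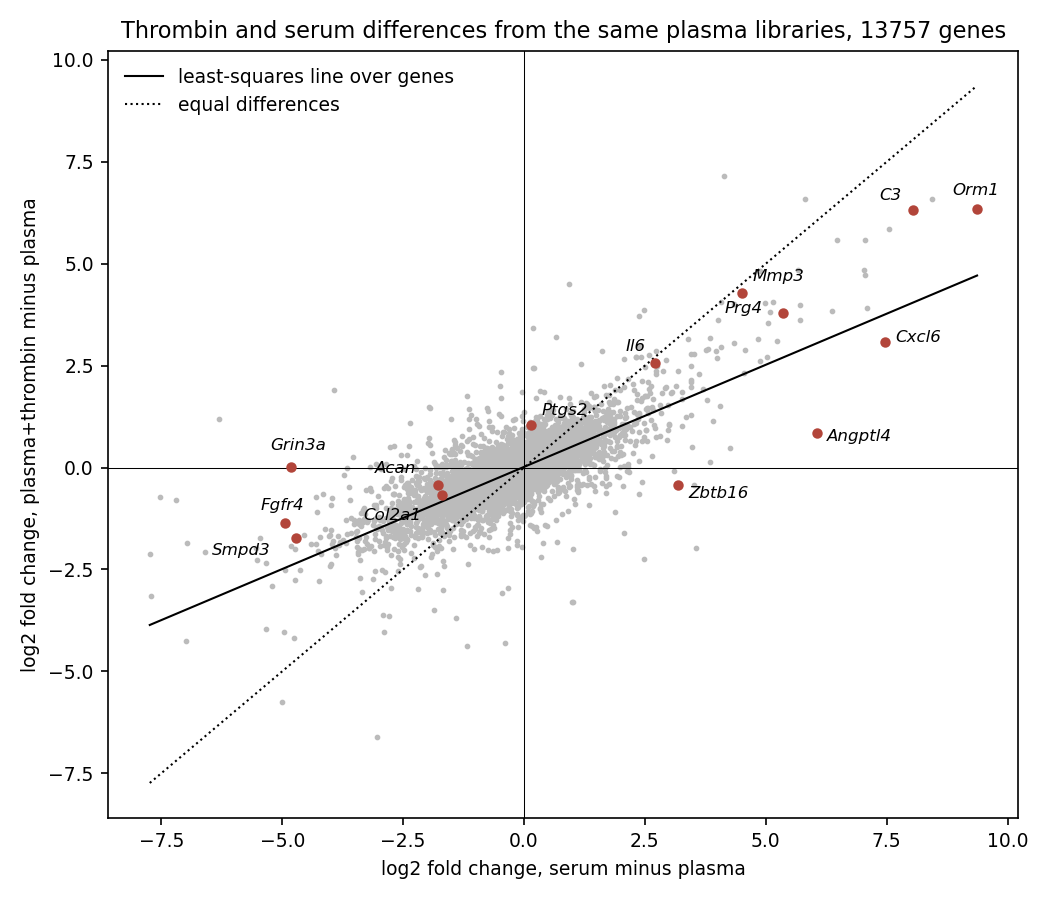
Log2 fold change of plasma plus thrombin minus plasma (vertical) against serum minus plasma (horizontal) for 13757 genes, with the least-squares line (slope 0.501) and a dotted line of equal differences. Mmp3 and Il6 lie near the dotted line, Angptl4, Zbtb16 and Grin3a lie within 1 of the horizontal zero line, and both differences share the same 3 plasma libraries.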

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

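The genes left out because they rest on 1 library were chosen after seeing the data, and every other alternative beforehand. The numbers of called genes stayed within 1.5 times under every alternative except a minimum 2-fold change, which left 1825 genes for plasma against serum, 702 for plasma plus thrombin against plasma and 723 against serum, by its own construction. Leaving out each library in turn gave 6592 to 6989, 2968 to 4020 and 3013 to 4059 genes. The replicate numbers showed no clear pairing of the samples. Deviations of libraries with the same number correlated between -0.12 and 0.137, and 5 of 9 libraries correlated best with their own number. A weak pairing is not excluded. The replicate block gave 7724, 4421 and 4327 genes, more than the 7383, 4018 and 3979 without it. The slope of the thrombin on the serum difference was 0.4925 for genes with a mean of at least 100 counts and 0.481 to 0.5247 with a library left out. The Pearson correlation was 0.5882 without a filter, 0.8191 with a stricter filter, 0.826 for genes with at least 100 counts, 0.6181 with DESeq2, 0.7969 with only the 6 libraries compared and 0.731 to 0.7814 with a library left out. The Spearman correlation was 0.6442, 0.8054, 0.8199 and 0.6496 under the first 4 of these and 0.7332 to 0.7812 with a library left out. The filters change which genes enter, and the cause of the other shifts was not tested. No named gene or list that was called changed its direction, but the balance of higher and lower calls turned with the scaling in each comparison. The report gives this against serum, and plasma plus thrombin against plasma had 2210 higher and 1898 lower with library size alone and 2123 higher and 1871 lower on log2(FPKM + 1), and kept its direction with upper quartile scaling (1897 and 2112). For plasma against serum it was also 3590 higher and 3849 lower without the 20 most abundant genes and 3758 higher and 4069 lower with only the 6 libraries compared. Named genes kept their side of the threshold in 3870 tests under the alternatives and lost it in 96, and the fixed lists kept it in 822, passed it in 2 and lost it in 9 by camera with the preset correlation and kept it in 52 and lost it in 8 with an estimated one. By fry, which asks another question, they kept it in 40 and passed it in 20. Genes with few counts were recovered less often in the simulation of the methods, in which far fewer genes were changed than were called in the data.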

Other observations

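The reading of the simulations with shared libraries and the mixture test were chosen after the results they bear on were seen. So were the returned-share tests, their division by list and the count of splits. The camera tests on unseen list members and the test on gene length were written before their results. All genes named here were chosen after their values were seen unless the report names them.

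In plasma plus thrombin 339 genes lay beyond both other groups by edgeR's test, 233 higher and 106 lower. Grem1, a secreted antagonist of bone morphogenetic proteins, stood at 403 ± 49 CPM against 166 ± 15 in plasma and 161 ± 2.5 in serum. The transcription factor Foxq1 stood at 45.7 ± 5.0 CPM against 14.1 ± 0.79 and 16.8 ± 0.77, and Scube3 at 45.6 ± 2.5 CPM against 7.80 ± 0.57 and 17.7 ± 2.5. The lactate transporter Slc16a3 was 2.20-fold higher than in plasma and 3.64-fold higher than in serum, and Spp1, a secreted matrix protein also known as osteopontin, was 2.36-fold and 1.98-fold higher. The gelatinase Mmp9 reached 6.75 ± 0.93 CPM, against 0.842 ± 0.26 in plasma and 4.45 ± 0.41 in serum.

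The position of plasma plus thrombin between plasma and serum was weighed against 2 technical explanations. Random spread of the shared plasma libraries does not account for it as a whole, because the covariance of both differences was 0.3893 against at most 0.0309 in simulations with no effect. A shift common to all plasma libraries would also enter both differences and was not simulated. A mixture of RNA from serum and plasma cultures would place each gene between both at 1 share, yet 339 genes lay beyond both, against at most 20 in simulated mixtures, and the share that fits Mmp3 is 0.838 where that for Angptl4 is 0.0119. An effect of thrombin in plasma remains a hypothesis. The series holds no culture with thrombin and no plasma, so an action of thrombin on the cells and one through products it makes in plasma may both stand.

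Several genes induced by glucocorticoids or by fatty acids through PPAR were high in serum and returned little with thrombin. Fkbp5 stood at 159 ± 5.2 CPM in serum, 40.0 ± 0.99 in plasma and 52.0 ± 4.1 in plasma plus thrombin, and Cpt1a at 144 ± 6.3, 34.0 ± 2.6 and 35.2 ± 2.6. Not all picked targets did so. On the log2 scale Mt1 changed by -2.366 in plasma against serum and by 1.18 with thrombin, and Mt2A by -2.475 and 1.1. In plasma against serum, 16 of 24 listed PPAR targets were called lower and 5 higher. For glucocorticoid targets it was 9 and 2 of 14. Over the 25 members lower in plasma the median return was 13.9%, but most were picked for this pattern. Of those not looked at beforehand, the 5 PPAR targets returned a median of 17.4%. This was below the 5th percentile (31.9%) of 10000 lists matched on serum difference and level. The matched lists drew genes independently, whereas targets of 1 pathway may move together, so this position may be too extreme. The 5 targets also differed, as Hadhb changed by 0.3059 and Decr1 by -0.2458 on the log2 scale with thrombin. The 2 glucocorticoid targets, Cebpd and Nfil3, returned a median of 61.7%, above the matched median of 53.9%, so the low return is not shown for glucocorticoid targets beyond the genes picked for it, and 2 genes are too few to decide. Whether glucocorticoid or PPAR signalling is the source may not be settled here: the 6 and 10 unseen targets had medians of -0.059 and -0.185 in plasma minus serum and did not pass limma's camera (adjusted p = 0.237 for both), although the unseen PPAR targets were lower with plasma plus thrombin than in serum (adjusted p = 0.00972, and unadjusted p = 0.111 with an estimated correlation in limma's camera).

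Imprinted genes such as Zim1 (110 ± 12 CPM in plasma, 5.51 ± 0.87 in serum), Peg3, Mest and Igf2 were higher in plasma, and 19 of 29 list members rose while 4 fell. A trend on gene length and level does not account for this, since the median of 0.41 was 0.438 after its removal. The choice of members may: the 12 members not looked at beforehand had a median of 0.27 with an adjusted p = 0.69 by limma's camera, 5 higher and 3 lower, with Dio3 down 7.07-fold. The pattern is therefore not shown for imprinted genes as a class, and no biological explanation was tested.

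Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05, and the real split was the 1 with the most genes in each. The real counts were 7383, 4018 and 3979, and the highest of the other splits gave 0, 1 and 1. Each other split mixes libraries of both conditions, so the real difference becomes spread within its groups. Few calls were therefore bound to result, and no conclusion is drawn from these counts.

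Among single genes, 30 rested on 1 library and 13 of these were called in some comparison. Nupr1l1 stood at 37.7 CPM in plasma plus thrombin replicate 2 and at most 1.498 CPM in the other 8 libraries, and Aldh18a1 at 39.2 CPM in serum replicate 3 and at most 1.162 CPM elsewhere.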
